A study of Homo sapiens with 335 samples.

How the data were processed

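RNA was measured by 3′ digital gene expression, which counts unique molecular identifiers at transcript ends, in 335 wells of one plate. The wells hold 7 breast cancer models, each under 15 conditions for 6 h. Lysates were barcoded by well during template-switching reverse transcription, pooled and made into Nextera libraries, per the labels' protocols. The deposited matrix holds raw counts per gene and well, aligned to GRCh38 per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. The file's own name calls the matrix filtered, and the filter is not stated. It listed 9276 genes, of which the lowest total was 217 counts and the lowest number of wells with a count was 49.

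A line of the matrix that names no gene, a sum exceeding the listed genes' total by 1.67% to 3.85% (median 2.71%), was left out of library sizes and tests. XIST, TSIX and Y-linked genes, 2 of those listed, were left out of all work, which left 9274 genes. All 9276 gene identifiers matched GENCODE release 29, from which symbols and coordinates were taken. Genes with near-identical copies, such as histone, ribosomal protein and mitochondrial pseudogene transcripts, are uncertain, since the counting rule is not stated.

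Total counts per well ranged from 71249 to 614581, with a median of 246250, and the median gene had 7 counts per well. Counts were summed over the wells of each model and condition, which gave 105 libraries of 334130 to 2336380 counts (median 794811). Pairs of wells from the same group spread beyond counting error, with a chi-square per degree of freedom of 1.048 to 3.929 (median 1.258, 397 pairs). The 10 most abundant genes took a median of 8.54% of a well's counts and at most 16.75%.

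Comparisons across models used the 105 summed libraries, with the model as a block, in edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr on the design, glmQLFit with robust estimation and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. Of the 9274 genes, 9273 were tested. Each comparison uses 7 models and the fit's standard errors. Comparisons within a model used the same test on counts per well, with all wells of that model sharing 1 estimate of the spread. Dependence on the model was tested as the model-by-treatment interaction, with 6 degrees of freedom, on the DMSO wells and the wells of 1 drug at 1 µM. Wells were not stated to be separate cultures, so p-values over wells measure only the spread between these samples, which may be technical. Each condition lay in the same plate rows in all models (DMSO in 6 of 16, each treatment in 3, and 2 for palbociclib at 0.3 µM in Hs578T), so tests over models do not exclude an effect of plate row. The labels carry no replicate numbers, and wells were numbered in the order of the deposited records.

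Gene lists were tested with camera (limma 3.58.1) on the fit across models, with a preset correlation of 0.01 and again with the correlation estimated from the data. Adjustment was over 20 lists and all comparisons against DMSO, or all between drugs. A list needed 5 measured members, and 3 lists had fewer. The mean log2 fold change of a list's members per model was tested with an exact two-sided sign-flip test over the 7 models (128 arrangements, smallest p 0.0156). Differences of list means between drugs were paired by model, in 238 tests, with a Hodges-Lehmann interval of 95.3% coverage. Within a model, the mean log2 CPM of the members per well (prior count 2) was compared between 3 and 6 wells by an exact two-sided permutation test over 84 splits, in 189 tests with a smallest p of 0.0119. The dependence of a list on the model was tested by permuting residuals over wells 100000 times, on the members measured in all 7 models. The log2 ratio of mean total counts was tested with the same sign-flip test. Shared effects of drugs were measured as the correlation and covariance of log2 fold changes across genes. Beside them stand 12 simulations of unchanged groups on the same DMSO libraries and splits of the 6 DMSO wells into 3 and 3.

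The lists, with measured of all members, were replication and G1/S genes (53 of 55), G2 and mitosis genes (40 of 40), short-lived and immediate-early transcripts (40 of 49), p53 targets (21 of 26), HEXIM1 with polyadenylated histone transcripts (14 of 18), sterol synthesis (27 of 30), lysosome and autophagy (31 of 35), the ATF4 amino acid response (23 of 25), endoplasmic reticulum stress (17 of 18), heat shock (16 of 18), oestrogen receptor targets (20 of 22), interferon and antigen presentation (16 of 30), ribosomal proteins (48 of 49), mitochondrial mRNAs (13 of 13), nuclear oxidative phosphorylation genes (39 of 40), transcription and splicing machinery (30 of 32), NF-κB targets (15 of 22), aryl hydrocarbon receptor targets (4 of 8), the CDK4/6 axis (17 of 20, gene by gene), and markers of fibroblasts (10 of 12), leukocytes (3 of 12), endothelium (1 of 10), luminal cells (12 of 12) and basal or mesenchymal cells (12 of 12).

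Lists, tests and the rule for named genes were fixed before the data were examined. The rule named, per comparison with DMSO at 1 and 3.16 µM, up to 10 genes that rose and 10 that fell most among those past the threshold with a mean log2 CPM of at least 4 and the same direction in at least 6 models. Between drugs it named 8 and 8, within a model 4 and 4 (log2 CPM of at least 5), for model dependence the 10 smallest adjusted p-values, and for each list the 4 members with the smallest adjusted p-values. CDK4, CDK6, CCND1, CCNE1, CCNE2, RB1, E2F1, CDKN1A, MYC, MCL1 and HEXIM1 were always included. Genes named at 0.1 and 0.3 µM, and the splicing genes followed over doses, were chosen after their values were seen.

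Alternatives were RLE size factors, library size without TMM, no filter beyond 1 count, DESeq2 1.42.0, wells not summed, each model or replicate left out in turn, and the 41 wells of the outer plate rows left out. Leaving out the 15 wells under 120000 counts, plate row as a term in fits of wells not summed, wells paired by plate row, and all tests of palbociclib at 0.3 µM in PDX-B were added after seeing the data. In that fit 380 of 7119 genes depended on plate row, as did the total counts (F = 5.34 over 335 wells), with 1 row effect for all models, and whether it differs between models was not tested. Other splits of the wells were drawn for every count: 28 across models, of 64 that exchange the 2 summed libraries in some of the models, and all 84 of the wells within a model. The tests were tested on simulated data drawn from the real means, with 200 genes changed. Across models, 93% of genes changed by 1 and 38% of those changed by 0.5 on the log2 scale were recovered, with 8 false calls among 9273 genes. Within MCF7 the shares were 50% and 5.4% (6 false calls among 5669 genes), and for model dependence 31.2% and 5.2% (4 among 6405). With no gene changed, no call was made across models or in MCF7.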

Results

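Transcripts were counted in 7 breast cancer models after 6 h with DMSO or 1 of 4 kinase inhibitors. Abemaciclib, palbociclib and ribociclib inhibit CDK4 and CDK6, the kinases that phosphorylate RB1 before S phase. Alvocidib inhibits many cyclin-dependent kinases, among them CDK9, which releases paused RNA polymerase. MCF7 and T47D are luminal, oestrogen receptor-positive lines, and BT549, Hs578T and HCC1806 are basal or triple-negative lines, of which BT549 is known to lack functional RB1. The other models, PDX-A and PDX-B, came from patient-derived xenografts. The CDK4/6 inhibitors were given at 0.1, 0.3, 1 and 3.16 µM and alvocidib at 0.1 and 1 µM. Each model had 6 DMSO wells, and each treated group had 3 wells, except palbociclib at 0.3 µM in Hs578T, which had 2. Each condition otherwise lay in the same plate rows in every model, so tests over models do not separate plate row from condition. Of 7119 genes 380 depended on plate row. In a fit of single wells with plate row as a term 166 results for named genes were kept and 45 lost, as were 6 of 62 list calls. Throughout, ± after a log2 fold change is the standard error of the edgeR fit over 7 models, and adjusted p-values are from edgeR's quasi-likelihood test unless another test is named.

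Comparison with DMSO asked which transcripts each drug and dose changed. Abemaciclib and alvocidib at their highest doses changed 2445 and 4450 of the 9273 genes tested. Palbociclib and ribociclib changed at most 15 at any dose in the joint fit of all conditions. With abemaciclib no gene rose and 11 fell at 0.1 µM, 4 rose and 24 fell at 0.3 µM, 404 rose and 373 fell at 1 µM, and 1371 rose and 1074 fell at 3.16 µM. With alvocidib 350 rose and 316 fell at 0.1 µM, and 2352 rose and 2098 fell at 1 µM. With palbociclib 2 rose and 3 fell at 0.3 µM, none rose and 2 fell at 1 µM, and 3 rose and 12 fell at 3.16 µM. With ribociclib no gene rose, and 1 fell at 0.3 µM, 2 at 1 µM and 10 at 3.16 µM. At 0.1 µM edgeR and DESeq2 both called 0 genes for palbociclib and ribociclib, with 307 and 348 genes at an unadjusted p under 0.05, against 464 that chance gives. In a fit of single wells the counts were 25, 79, 1029 and 2419 for abemaciclib in order of dose, 0, 52, 25 and 47 for palbociclib, 0, 6, 15 and 25 for ribociclib, and 1035 and 3706 for alvocidib. Plate row as a term in that fit lowered them to 6, 19, 682 and 2351, to 0, 1, 2 and 13, to 0, 1, 1 and 5, and to 269 and 3135.

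**Figure D1:**
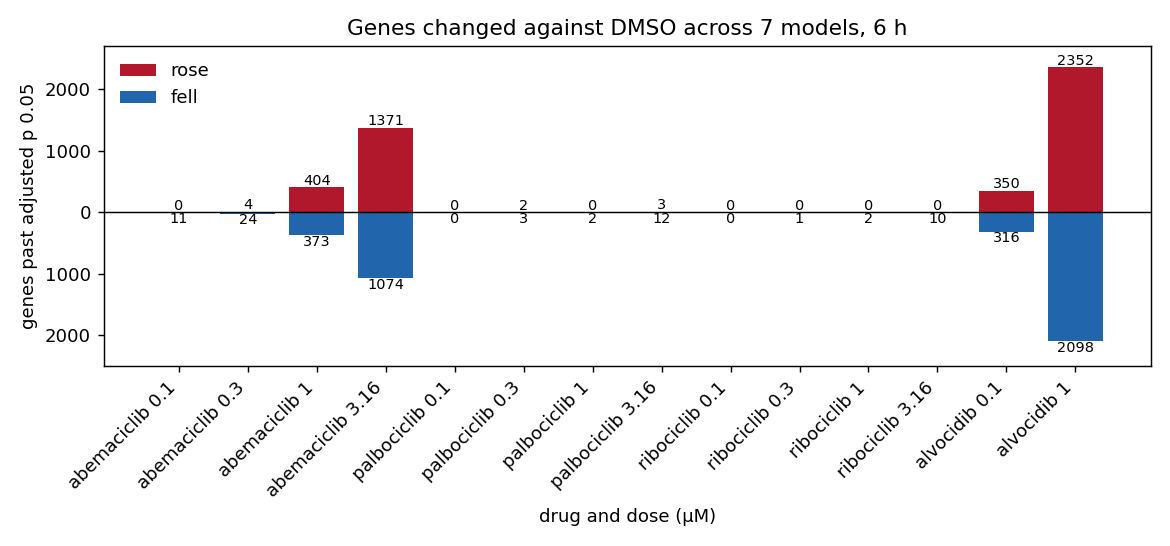
Genes past an adjusted p of 0.05 (vertical axis, number of genes, rises above 0 and falls below it) for each drug and dose in µM (horizontal axis) against DMSO over 7 models. In this fit of all conditions together abemaciclib at 3.16 µM changed 2445 genes and alvocidib at 1 µM 4450, while no dose of palbociclib or ribociclib changed more than 15.

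The split between rises and falls depended on the scaling. With library size alone the median of all genes shifted by −0.09 for abemaciclib at 1 µM, −0.21 at 3.16 µM, −0.09 for alvocidib at 0.1 µM and −0.31 at 1 µM. Calls then became 198 rises and 688 falls, 391 and 2443, 115 and 590, and 571 and 3955 in the same order. For abemaciclib at 0.1 µM they became 1 and 8, for palbociclib at 0.3 µM 1 and 3, and with RLE factors ribociclib at 0.3 µM had 1 and 1. Without MCF7 the count for abemaciclib was 12 at 0.3 µM and 296 at 1 µM, that for alvocidib at 0.1 µM 292, and at 3.16 µM palbociclib had 2 and ribociclib 0. Without PDX-A abemaciclib at 0.1 µM had 22, and at 3.16 µM palbociclib had 42 and ribociclib 19.

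Genes of DNA replication and the G1/S transition, most of them driven by E2F factors, were lower with all 3 CDK4/6 inhibitors at every dose. The median log2 change of the 53 measured members was −0.38 with palbociclib at 1 µM (camera adjusted p = 2.18e-55, or 7.27e-08 with an estimated correlation), −0.32 with ribociclib (1.13e-42 and 2.48e-06) and −0.26 with abemaciclib (4.96e-14 and 0.0154). At 3.16 µM the medians were −0.39, −0.39 and −0.25, and the abemaciclib call was lost with an estimated correlation (adjusted p = 8.74e-06, against 0.215). At 0.1 µM the medians were −0.22 with palbociclib (1.21e-24), −0.17 with ribociclib (4.12e-11) and −0.31 with abemaciclib (2.61e-38), and at 0.3 µM −0.29 (6.35e-26), −0.27 (5.65e-32) and −0.30 (3.2e-33). Over all genes, 2 members fell with palbociclib at 1 µM and 5 at 3.16 µM, 1 and 9 with ribociclib, and 15 and 17 with abemaciclib, while 1 member rose with abemaciclib at 3.16 µM.

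PCNA, the sliding clamp of DNA polymerase (ENSG00000132646, GRCh38 chromosome 20, 5114953 to 5126626), was called with all 3 drugs, as were CLSPN, a replication checkpoint adaptor, and MCM10, which activates the replicative helicase. PCNA fell by 0.52 ± 0.11 with palbociclib at 1 µM (adjusted p = 0.0194) and by 0.5 ± 0.11 with ribociclib (0.0498). Abemaciclib lowered it already at 0.1 µM, by a log2 change of −0.55 ± 0.11 (0.00322). CLSPN fell by 0.69 ± 0.14 with palbociclib at 1 µM (0.0194). With palbociclib at 3.16 µM MCM10 fell by 0.78 ± 0.15 (0.00133), and the nuclease EXO1, the polymerase subunit POLD3, ATAD2 and the cohesin acetyltransferase ESCO2 fell by 0.68, 0.54, 0.53 and 0.53. With ribociclib at 3.16 µM the helicase subunits MCM6, MCM2 and MCM7 fell by 0.79, 0.62 and 0.49, GINS2 by 0.69, MCM10 by 0.7 and CDK2 by 0.55 ± 0.13 (0.022). RRM2, the small subunit of ribonucleotide reductase, fell by 0.48 ± 0.11 with palbociclib at 3.16 µM (0.0312), and DTL (−0.95, 0.0893) and MCM7 (−0.45, 0.0893) were not past the threshold with palbociclib at 1 µM. The calls at 3.16 µM of EXO1, POLD3 and ATAD2 with palbociclib and of MCM6, MCM2, MCM10 and CDK2 with ribociclib were lost with plate row as a term. Those of PCNA and CLSPN were kept.

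**Figure D2:**
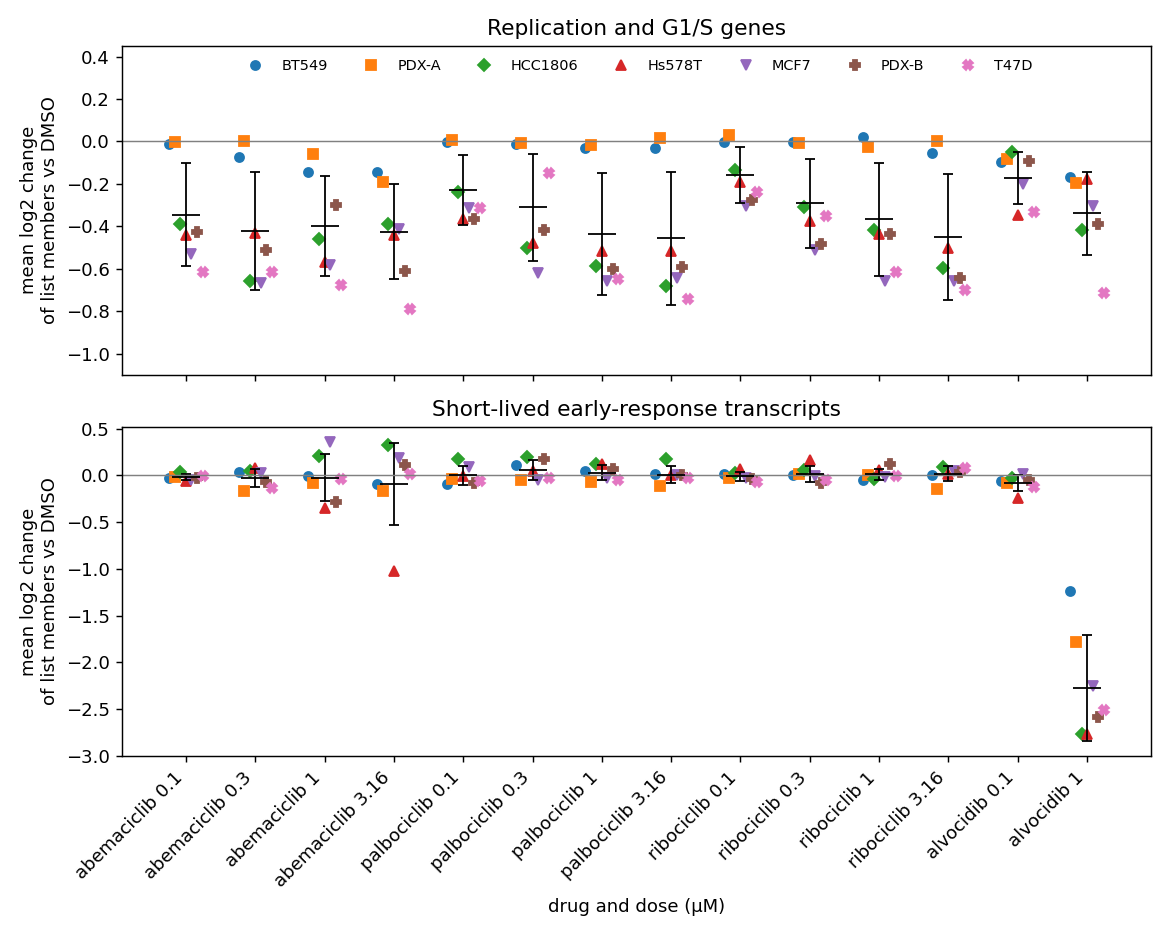
Mean log2 change against DMSO (vertical axis) of the members of 2 gene lists for each drug and dose in µM (horizontal axis), with a point per model and bars at the mean ± SD of 7 models. Replication genes lay near 0 in BT549 and PDX-A with palbociclib and ribociclib, and short-lived transcripts fell in each model with alvocidib at 1 µM.

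Genes of G2 and mitosis fell with abemaciclib. Of 40 members, 25 fell at 1 µM and 33 at 3.16 µM with none rising, with medians of −0.45 (camera adjusted p = 4.39e-26, or 0.000516 with an estimated correlation) and −0.58 (2.38e-20 and 0.00236). NDC80, a kinetochore subunit, fell by 0.83 ± 0.14 at 1 µM (7.39e-06), the spindle checkpoint kinase TTK by 0.75 ± 0.14 (4.05e-05) and CDK1, the mitotic kinase, by 0.46 ± 0.08 (4.36e-05), each in 7 of 7 models. At 3.16 µM TTK fell by 1.42 ± 0.16 and the mitotic kinase AURKA by 1.26 ± 0.15 (2.09e-12), from 66.7 ± 25.3 CPM (SD, n = 7 models) to 28.5 ± 15.9. Medians were −0.14 at 0.1 µM (1.08e-07, against an adjusted p = 0.124 with an estimated correlation) and −0.19 at 0.3 µM (8.23e-15 and 0.0131). With palbociclib the medians of −0.10 at 1 µM and −0.12 at 3.16 µM were called (3.58e-05 and 4.67e-10), and so were −0.07, −0.05 and −0.09 with ribociclib at 0.3, 1 and 3.16 µM (0.00721, 0.0132 and 0.000311). None of these 5 calls held with an estimated correlation (adjusted p = 0.288, 0.0501, 0.658, 0.691 and 0.425). CDK1 fell by 0.36 ± 0.08 with palbociclib at 3.16 µM (0.00453).

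Among the genes that rose with abemaciclib at 1 µM was GDF15, a secreted stress cytokine (ENSG00000130513, GRCh38 chromosome 19, 18374731 to 18389176). It had a log2 change of 1.33 ± 0.17 (adjusted p = 1.63e-09), with a mean of 31.7 ± 38.5 CPM with DMSO (SD, n = 7 models). CDKN1A, the CDK inhibitor p21 (chromosome 6, 36676460 to 36687339), rose by 1.13 ± 0.19 (8.76e-06), SESN2, an inhibitor of mTORC1, by 0.83 ± 0.22 (0.00601; 0.67 and not past the threshold with plate row as a term), and AEN, a nuclease induced by p53, by 0.8 ± 0.18 (0.00151). The circadian repressor BHLHE40, the growth factor EREG, ZNF580 and the small MAF factor MAFG rose by 0.86, 0.79, 0.79 and 0.78. Among falls were MEPCE, which caps the 7SK RNA that holds CDK9 inactive, (−1.57 ± 0.26, 3.09e-06), UBALD2 (−1.89 ± 0.3, 1.44e-06), the transcription factor NKX3-1 (−1.49 ± 0.24) and CITED2, a p300-binding regulator (−1.05 ± 0.17). HIST1H1A, a linker histone with close paralogs, GNB1L, MEIS1, TLE3 and CBR3 fell by 1.1, 1.24, 1.12, 1.09 and 1.05. HEXIM1, which inhibits CDK9 together with 7SK, fell by 0.63 ± 0.22 (0.046), and CCNE2, cyclin E2, by 1.01 (0.0271).

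At 3.16 µM abemaciclib changed GDF15 by 2.1 ± 0.16 (adjusted p = 4.62e-21), to a mean of 143 ± 168 CPM (SD, n = 7 models), CDKN1A by 1.96 ± 0.18 (6.21e-19) and AEN by 1.46 ± 0.17. TRIB3, a pseudokinase induced by ATF4, rose by 1.46 ± 0.14 (8.76e-16), the early-response factor EGR1 by 1.48 ± 0.22 (6.12e-08), JUNB by 1.15, and MAFG, EREG, BHLHE40 and ZBTB43 by 1.49, 1.31, 1.28 and 1.2. MEPCE fell by 2.19 ± 0.31 (1.96e-09), to 4.27 ± 2.51 CPM from 19.5 ± 8.95 (SD, n = 7 models). HJURP, which loads the centromeric histone, fell by 1.64 ± 0.18, IRS1, the insulin receptor substrate, by 1.51 ± 0.26, HEXIM1 by 1.31 ± 0.25 (7.44e-06), and the ephrin EFNA4 (−1.83), ARL4A (−1.8), PIGBOS1 (−1.69), CBR3 (−1.67), MTFR2 (−1.64), MAGEF1 (−1.57) and ZBED5 (−1.53) fell as well.

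Among the fixed lists, targets of ATF4, the factor of the amino acid stress response, rose with abemaciclib. Of 23 members, 12 rose at 1 µM and 14 at 3.16 µM with none falling, with medians of 0.31 (camera adjusted p = 8.09e-11) and 0.40 (2.93e-07). GARS, a tRNA synthetase, rose by 0.47 ± 0.08 at 1 µM (1.48e-05), the amino acid transporter subunit SLC3A2 by 0.45 ± 0.09 (0.000359) and PSAT1, of serine synthesis, by 0.39 ± 0.09 (0.00164). TRIB3 rose by 0.73 ± 0.15 (0.000369), in 4 of 7 models. Lysosomal and autophagy genes rose in 5 of 31 at 1 µM and 19 of 31 at 3.16 µM, with medians of 0.21 (0.000107) and 0.38 (2.42e-08). CTSD, a lysosomal protease, rose by 0.55 ± 0.07 at 3.16 µM (1.73e-10), ATP6V0E1, of the proton pump, by 0.45 ± 0.06 (6.27e-11) and the folliculin partner FNIP1 by 0.91 ± 0.13 (5.13e-09). Endoplasmic reticulum stress genes, most of them chaperones or folding factors, rose in 3 and 8 of 17, with medians of 0.22 (0.000242) and 0.27 (0.00278, against an adjusted p = 0.0564 with an estimated correlation); PDIA6 rose by 0.33 ± 0.08 at 1 µM (0.00195). Their call at 3.16 µM was lost with plate row as a term (0.0835). Sterol genes were called at 3.16 µM only, with 14 of 27 rising and a median of 0.33 (4.41e-05 and 0.0347), led by the desaturase SCD (0.97 ± 0.08, 3.81e-24) and MSMO1 (0.92 ± 0.1). The p53 targets were not called as a list at either dose (adjusted p = 0.567 and 0.537), with 4 of 21 rising and 1 falling at 1 µM, and 4 and 3 at 3.16 µM.

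At lower doses the ATF4, reticulum stress and lysosomal lists were called with abemaciclib at 0.3 µM, with medians of 0.13 (camera adjusted p = 0.000146), 0.15 (2.65e-05) and 0.11 (0.00547, against an adjusted p = 0.126 with an estimated correlation). Reticulum stress genes were called with palbociclib at 0.3 µM (0.16, 0.000369), at 1 µM (0.11, 0.00732, against an adjusted p = 0.0825 with an estimated correlation) and at 3.16 µM (0.04, 0.0253, against 0.169), and with ribociclib at 3.16 µM (0.13, 1.98e-05). ATF4 targets were called with palbociclib at 3.16 µM (0.13, 4.33e-05), where NUPR1, a stress-induced chromatin protein, rose by 0.39 ± 0.09 (0.0176) and, outside the lists, TTC14 by 0.45 (0.0176). Plate row as a term ended the reticulum stress calls with palbociclib at 1 and 3.16 µM (0.0753 and 0.135).

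**Figure D3:**
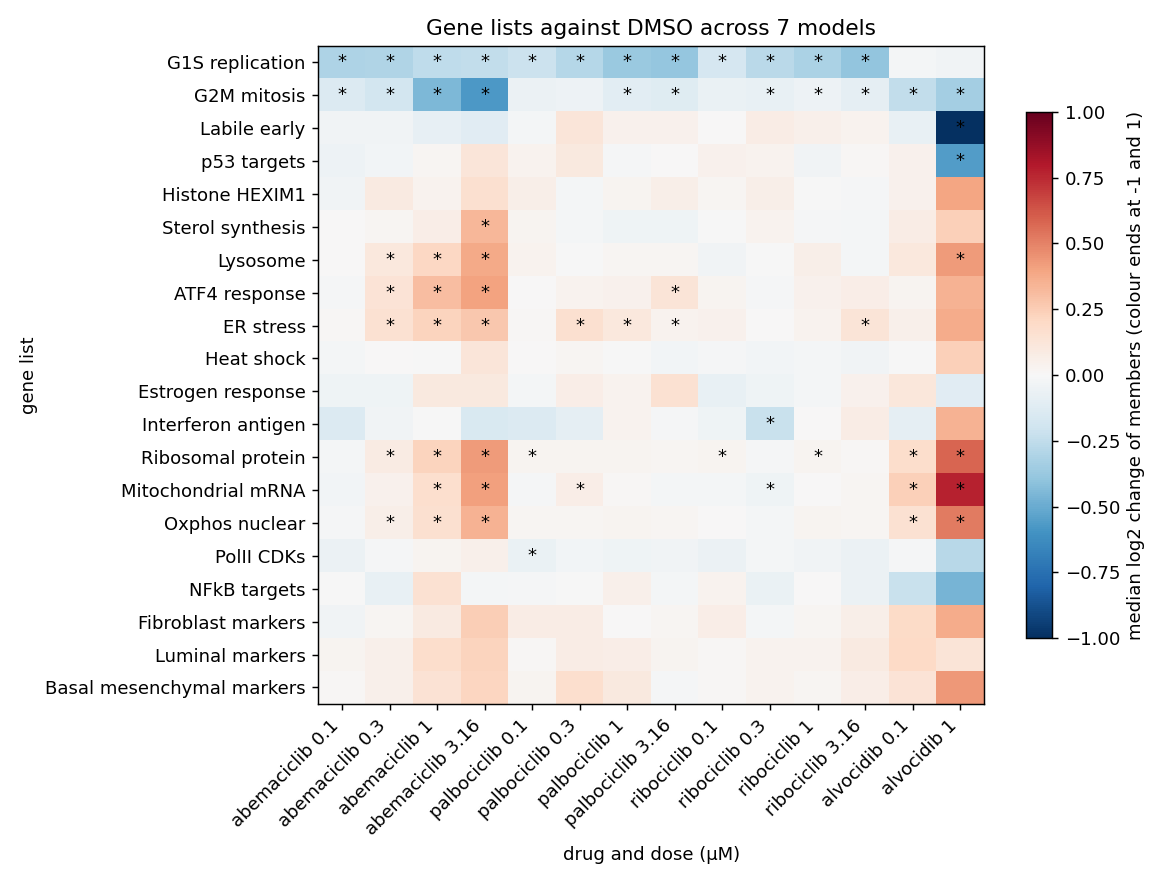
Median log2 change of the members of 20 gene lists (vertical axis) for each drug and dose in µM (horizontal axis) over 7 models, with colours ending at −1 and 1 and a star where camera's adjusted p was under 0.05. Replication genes were called with the 3 CDK4/6 inhibitors at each dose and not with alvocidib, for which short-lived transcripts lay at −1.86 at 1 µM.

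Among the few genes that abemaciclib changed at low doses were SRSF3, SRSF7 and HNRNPDL. These genes and their kinases were chosen after their values were seen, and the fixed list of transcription and splicing genes was not called with abemaciclib at any dose (camera adjusted p from 0.163 to 0.726). SRSF3, an SR splicing factor (ENSG00000112081, GRCh38 chromosome 6, 36594353 to 36605600), changed by −0.42 ± 0.09 at 0.1 µM (adjusted p = 0.0102), −0.72 ± 0.09 at 0.3 µM (1.43e-08), −1.03 ± 0.09 at 1 µM (3.11e-14) and −0.85 at 3.16 µM. SRSF7, of the same family, changed by −0.53, −0.7, −1.02 and −1.13, and HNRNPDL, an RNA-binding protein, by −0.41, −0.78, −1.08 and −0.92, and the 3 genes were lower in 7 of 7 models at each dose. CLK1, a kinase of SR proteins (ENSG00000013441), was not past the threshold at 0.1 µM (0.32, 0.885) and rose by 0.77 ± 0.14, 0.88 ± 0.15 and 0.71 at the higher doses, and CLK4 rose by 0.67 ± 0.15 at 0.3 µM (0.00558) and 0.83 ± 0.15 at 1 µM but not at 3.16 µM (0.1 ± 0.18, 0.715, higher in 3 models and lower in 4). With plate row as a term SRSF3 changed by −0.39, −0.69, −1.05 and −0.86 over the doses (adjusted p of at most 7.65e-05), and CLK1 by 0.67 at 0.3 µM (0.0341). In that fit the call of CLK4 at 0.3 µM was lost (0.44, 0.452), as was that of CLK1 with palbociclib at 3.16 µM (0.56, 0.125). Palbociclib at 3.16 µM also raised CLK1, by 0.67 ± 0.14 (0.00255), and lowered SRSF7 (−0.57 ± 0.1, 0.00095) and SRSF3 (−0.38 ± 0.09, 0.0202), while ribociclib at 3.16 µM left CLK1 (−0.13), SRSF3 (−0.23, 0.748) and SRSF7 (−0.26, 0.748) short of it. Alvocidib at 0.1 µM lowered SRSF3 by 0.77, SRSF7 by 0.65 and HNRNPDL by 1.06 ± 0.09 (3.88e-17), did not change CLK1 past the threshold (−0.22, 0.484), and at 1 µM lowered CLK1 by 1.59 ± 0.25 (9.89e-09).

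**Figure D4:**
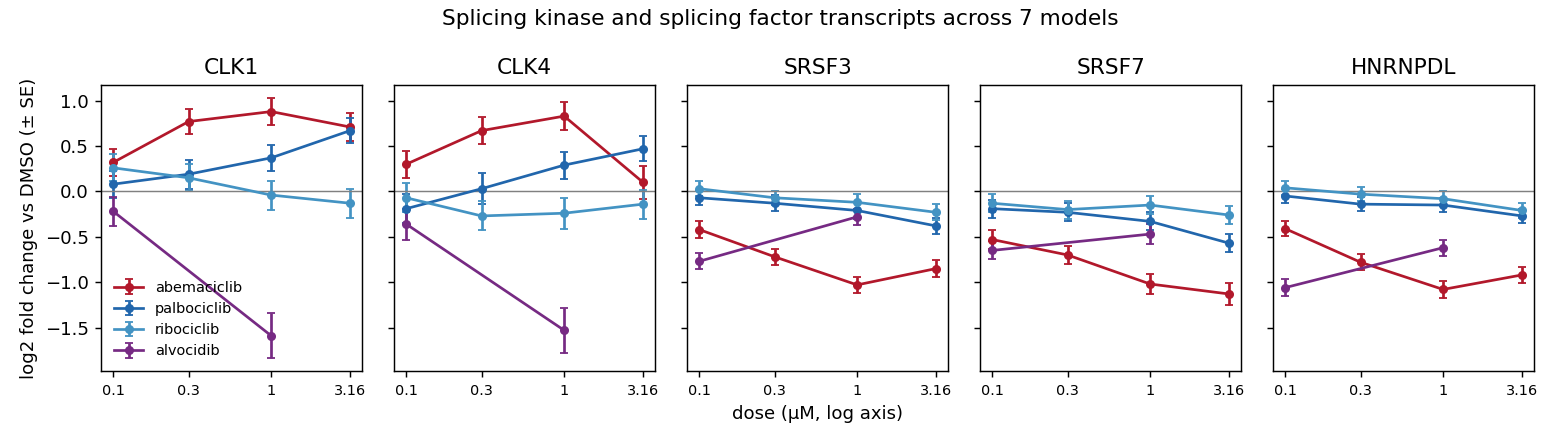
Log2 fold change against DMSO (vertical axis, ± SE over 7 models) of 5 genes by dose in µM (log horizontal axis), with a line per drug. SRSF3, SRSF7 and HNRNPDL fell with abemaciclib from 0.1 µM on, and CLK1 rose with abemaciclib and fell with alvocidib at 1 µM.

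Other genes called at low doses, also chosen after their values were seen, were few. Abemaciclib at 0.1 µM lowered the primase subunit PRIM1 by 0.81 ± 0.15 (adjusted p = 0.000756), HIST1H1A by 0.61, H1FX by 0.52, POLD3 by 0.49, the ubiquitin enzyme UBE2T by 0.37 and the checkpoint gene MAD2L1 by 0.33. At 0.3 µM it lowered CLSPN by 0.81 ± 0.14 (0.000468), MCM10 by 0.79, WDR76 by 0.77 and the helicase BRIP1 by 0.76, and raised the AMP transferase FICD by 0.77 ± 0.2 (0.047) and NUPR1 by 0.36 ± 0.09 (0.0409). Palbociclib at 0.3 µM lowered the kinetochore gene SPC24 by 0.52 ± 0.11 (0.0143) and raised MRFAP1 by 0.39 ± 0.08 (0.0143). Ribociclib lowered the linker histone HIST1H1A by 0.62 ± 0.11 at 0.3 µM (0.00109) and by 0.52 at 1 µM (0.0498). None of the genes named here for abemaciclib at 0.1 µM, for palbociclib and for ribociclib was called with plate row as a term, nor were MCM10, BRIP1 and FICD at 0.3 µM. Of the 11 calls of abemaciclib at 0.1 µM SRSF3, SRSF7, HNRNPDL and PCNA stayed.

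Alvocidib at 1 µM lowered short-lived transcripts. Of 40 immediate-early and other short-lived transcripts measured, 35 fell and none rose, with a median of −1.86 (camera adjusted p = 1.05e-17, or 2.48e-06 with an estimated correlation). MCL1, an anti-apoptotic protein (ENSG00000143384, GRCh38 chromosome 1, 150574551 to 150579738), fell by 2.52 ± 0.19 (6.47e-28), from 69.7 ± 28.4 to 11.7 ± 8.51 CPM (SD, n = 7 models). The early-response gene IER2 fell by 4.34 ± 0.42 (1.61e-19), the mRNA decay factor ZFP36L2 by 3.18 ± 0.19 (1.31e-36), the antiproliferative BTG1 by a log2 change of −2.56 ± 0.24, MYC by 1.31 ± 0.25 (5.87e-06), HEXIM1 by 1.71 ± 0.29 and CCNE1, cyclin E1, by 2.89 ± 0.53 (8.26e-07). FADD, an adaptor of death receptors, fell by 3.87 ± 0.39, CITED2 by 3.48 ± 0.28 and FOXA1, a luminal pioneer factor, by 3.43 ± 0.39, with TP53RK, WDR89, MTERF1, PPRC1, TENT5A and DKK1 between −3.41 and −3.85. The genes that rose most were CCDC80 (2.1 ± 0.16, 9.68e-21), NAV3 (1.76 ± 0.24), PLCG2 (1.65 ± 0.21), PIGF (1.05), C9orf16 (1.03), CYB5D2 (0.96), MGAT5, IL13RA1 and MUC1 (each 0.94), and the mitochondrial pseudogene MTCO2P22 (1.04).

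The p53 targets were lower with alvocidib at 1 µM, with 2 of 21 rising, 10 falling and a median of −0.56 (camera adjusted p = 0.00766, against an adjusted p = 0.121 with an estimated correlation); MDM2, the ubiquitin ligase of p53, fell by 0.69 ± 0.11 (1.24e-08). Mitotic genes had 20 of 40 falling and 1 rising (−0.34, 5.56e-05, against an adjusted p = 0.352 with an estimated correlation), led by cyclin F, CCNF (−2.13 ± 0.2, 2.27e-19), and PLK1 (−1.46 ± 0.19). Replication genes were not called (median −0.04, mean −0.27, adjusted p = 0.334): 10 rose, among them the thymidine kinase TK1 (0.56 ± 0.1, 1.03e-06), and 19 fell, among them the licensing factor CDT1 (−1.87 ± 0.27, 9.62e-10). Lysosomal genes rose in 19 of 31 and fell in 3 (0.42, 0.000652 and 0.0495). For ATF4 targets the median was 0.35 and the mean −0.18 (adjusted p = 0.749), with 12 rising and 7 falling, such as DDIT4 (−3.17 ± 0.39, 4.63e-11), an inhibitor of mTORC1. For reticulum stress genes the median was 0.37 and the mean −0.11 (0.272), with 11 rising and 4 falling, such as XBP1 (−1.53 ± 0.15).

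At 0.1 µM alvocidib raised the subunits of P-TEFb, the complex that drives transcript elongation. CCNT2 rose by 1.11 ± 0.17 (adjusted p = 4.21e-07), CCNT1 by 0.82 ± 0.12 (1.32e-07) and CDK9 by 0.89 ± 0.2 (0.00092), while CCNT1 fell by 1.56 ± 0.22 at 1 µM (1.3e-10). MEPCE fell by 1.6 ± 0.24 (3.32e-07), and EREG, ZNF580, ATAD1, MAFG, RBM14, CCNL2 and KLF7 rose by 1.13, 0.99, 0.96, 0.8, 0.8, 0.78 and 0.76. CBR3, SPDEF, RBM38, ATXN7L3B, HEATR6, UTP18, GNB1L and MTFR2 fell by 1.17, 1.07, 1.05, 1.03, 1.02, 0.99, 0.99 and 0.97. Mitotic genes had 10 of 40 falling (median −0.24, camera adjusted p = 1.14e-09, against an adjusted p = 0.0623 with an estimated correlation), replication genes 5 of 53 (−0.02, 0.0581) and lysosomal genes 4 rising and 1 falling (0.0581). Of the 666 calls 218 stayed in the fit of single wells with plate row as a term, and KLF7, RBM38 and GNB1L were lost.

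Transcripts of the translation and respiration machinery took a larger share of the counts with abemaciclib and alvocidib. Of 48 ribosomal protein genes 41 rose with abemaciclib at 1 µM, 47 at 3.16 µM, and 30 and 47 with alvocidib at 0.1 and 1 µM, with medians of 0.22 (camera adjusted p = 2.85e-38), 0.43 (2.18e-55), 0.18 (1.45e-25) and 0.58 (4.27e-45). The calls at 1 µM abemaciclib and 0.1 µM alvocidib were lost with an estimated correlation (adjusted p = 0.0501 and 0.154). Of 13 mitochondrial mRNAs 6, 12, 9 and 13 rose, with medians of 0.17 (3.27e-08, against an adjusted p = 0.148 with an estimated correlation), 0.41, 0.24 and 0.77, and MT-ND4 rose by 0.83 ± 0.05 with alvocidib at 1 µM (3.64e-35). Of 39 nuclear oxidative phosphorylation genes 12, 34, 10 and 34 rose, with medians of 0.16 (6.59e-12, against 0.138), 0.35, 0.15 (3.66e-10, against 0.202) and 0.52, and COX6C rose by 0.46 ± 0.06 with abemaciclib at 3.16 µM (2.19e-11). Scaled by library size alone the ribosomal medians were 0.13, 0.2, 0.09 and 0.23. Smaller shifts of these 3 lists, of 0.08 or less, were called with abemaciclib at 0.3 µM, palbociclib at 0.1 and 0.3 µM and ribociclib at 0.1, 0.3 and 1 µM, and none held with an estimated correlation.

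Total counts per well were lower with 3 of these 4 conditions, and not with alvocidib at 0.1 µM (−0.04, lower in 3 of 7 models, exact two-sided sign-flip p = 0.531). The mean log2 ratio to DMSO was −0.38 ± 0.17 (SD, n = 7 models) with abemaciclib at 1 µM, −0.47 ± 0.29 at 3.16 µM and −0.54 ± 0.31 with alvocidib at 1 µM, lower in 7 of 7 models each (exact two-sided sign-flip p = 0.0156, the smallest possible, adjusted p = 0.0729). The other conditions lay between −0.13 and 0.16 (exact p of at least 0.125). The share of mitochondrial mRNA was 4.93% with DMSO and higher by 0.28 and 0.68 points with abemaciclib at 1 and 3.16 µM and by 0.55 and 1.57 points with alvocidib at 0.1 and 1 µM, in 7 of 7 models each (exact two-sided p = 0.0156, adjusted p = 0.0547). These p-values treat the models as independent, although all models share the plate rows of a condition. DMSO wells in plate row I had a mean log2 total of −0.42 relative to the DMSO wells of their model (n = 7 wells), and the other plate rows lay between −0.08 and 0.12. With plate row as a term the totals were lower by 0.26 ± 0.11 (SE over wells, adjusted p = 0.0849) and 0.53 ± 0.1 with abemaciclib at 1 and 3.16 µM and by 0.41 ± 0.11 with alvocidib at 1 µM. The mitochondrial share was then higher by 0.21 ± 0.09 points with abemaciclib at 1 µM, where it was not past the threshold (adjusted p = 0.101), by 0.68 at 3.16 µM, and by 0.65 and 1.52 with alvocidib.

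**Figure D5:**
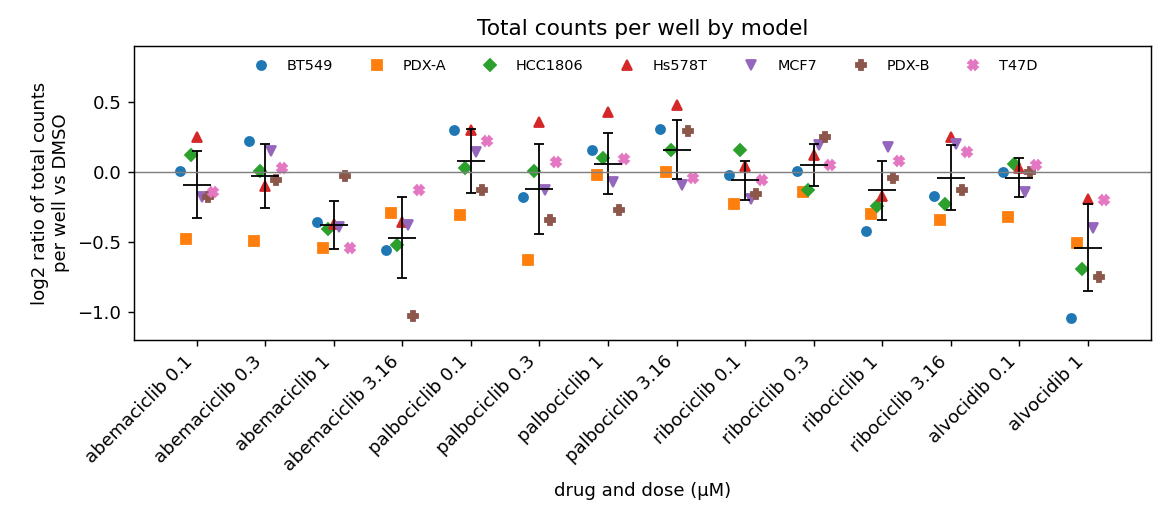
Log2 ratio of mean total counts per well against DMSO (vertical axis) for each drug and dose in µM (horizontal axis), with a point per model and bars at the mean ± SD of 7 models. All 7 models lay below 0 with abemaciclib at 1 and 3.16 µM and with alvocidib at 1 µM.

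The remaining lists held few calls across models. Interferon and antigen presentation genes were called with ribociclib at 0.3 µM (median −0.22, camera adjusted p = 5.56e-05, or 0.0423 with an estimated correlation), although no member of 16 passed, and in no other comparison with DMSO; B2M, the light chain of antigen-presenting molecules, rose by 0.6 ± 0.06 with alvocidib at 1 µM (7.63e-17). Transcription and splicing genes were called with palbociclib at 0.1 µM (−0.06, 0.0154 and 0.0234) and moved both ways otherwise, with 9 of 30 rising and 8 falling with abemaciclib at 3.16 µM (0.726) and 6 and 16 with alvocidib at 1 µM (0.166); the RNA helicase DDX5 fell by 0.62 ± 0.06 with abemaciclib at 3.16 µM (3.97e-16). Short-lived transcripts were not called with abemaciclib at 1 µM (0.907) or 3.16 µM (median −0.12, mean −0.02, upward in camera, 0.931), where 13 of 40 rose and 10 fell. HEXIM1 and histone genes were not called (0.567 with abemaciclib at 1 µM, 0.598 with alvocidib at 1 µM). Heat shock genes were not called (0.943 and 0.211 at the highest doses of abemaciclib and alvocidib), nor were oestrogen receptor targets (0.868 and 0.62), NF-κB targets (0.322 with alvocidib), or markers of fibroblasts (0.421 and 0.516), luminal cells (0.635 and 0.74) and basal or mesenchymal cells (0.576 and 0.343). Lists with 4, 3 and 1 measured members (aryl hydrocarbon receptor targets, leukocyte and endothelial markers) were too small to test. The calls of interferon genes with ribociclib at 0.3 µM (0.139) and of transcription genes with palbociclib at 0.1 µM (0.112) were lost with plate row as a term.

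The transcripts of the CDK4/6 axis were looked at gene by gene. With abemaciclib at 1 µM CDK4 (0.1 ± 0.19, adjusted p = 0.847), CDK6 (0.08), CCND1, cyclin D1 (0.13 ± 0.1, 0.467) and RB1 (0.09 ± 0.22, 0.887) were not past the threshold, and neither was E2F1 with palbociclib at 1 µM (−0.62, 0.715). CDK2 fell by 0.42 ± 0.13 with abemaciclib at 1 µM (0.025). At 3.16 µM CDKN2C (−0.84 ± 0.16, 4.95e-06), E2F7, RBL1, CDKN1B and E2F4 fell and E2F3 rose. With alvocidib at 1 µM CDKN1B, the CDK inhibitor p27, fell by 2.31 ± 0.4 (2.55e-07), and CDKN2A (0.61 ± 0.12) and CDK6 (0.51) rose.

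The comparison of abemaciclib with palbociclib asked where they differ at matched doses. At 0.1 µM edgeR and DESeq2 called 0 genes (402 at an unadjusted p under 0.05), 2 were higher and 15 lower with abemaciclib at 0.3 µM, 255 and 244 at 1 µM, and 1149 and 865 at 3.16 µM. At 1 µM GDF15 was higher with abemaciclib by 1.31 ± 0.18 (adjusted p = 2.79e-07), CDKN1A by 1.2 ± 0.22 (9.1e-05), AEN by 1.09 ± 0.21, SESN2 by 0.97 ± 0.25 and PPP1R15A, which reverses the stress block on translation, by 0.75. UBALD2 was lower (−1.86 ± 0.33), as were MEPCE (−1.36 ± 0.29, 0.0011), SGK1 (−1.1), CITED2 (−1.09), GNB1L (−1.33), FBXO8 (−1.28), MEIS1 (−1.27) and TLE3 (−1.12). At 3.16 µM CDKN1A was higher by 2.24 ± 0.21 (3.49e-18), GDF15 by 2.14 ± 0.17 and TRIB3 by 1.36 ± 0.15, and MEPCE (−2.15 ± 0.33) and ZFP36L2 (−1.49 ± 0.14) were lower. At 0.3 µM HNRNPDL (−0.64 ± 0.09, 2.86e-06) and SRSF3 (−0.6 ± 0.09, 3.59e-05) were lower with abemaciclib, and the 2 higher genes were MTPAP and MTRNR2L13. Scaled by library size alone, 118 genes were higher and 381 lower at 1 µM, and 331 and 2010 at 3.16 µM, and without MCF7 156 differed at 1 µM. Without PDX-A 3 differed at 0.3 µM. In a fit of single wells 3, 21, 620 and 1862 genes differed in order of dose, and 3, 3, 211 and 1408 with plate row as a term, those at 0.1 and 0.3 µM being SRSF3, SRSF7 and HNRNPDL. In that fit MTPAP and MTRNR2L13 at 0.3 µM and SESN2 and PPP1R15A at 1 µM lost their call.

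The same comparison with ribociclib gave 2 genes lower with abemaciclib at 0.1 µM, HNRNPDL (−0.45 ± 0.09, adjusted p = 0.00876) and SRSF3 (−0.45 ± 0.09, 0.0158). At 0.3 µM CLK4 and TMEM101 were higher and 7 genes lower, and at 1 µM 212 and 178, and at 3.16 µM 1125 and 831. CDKN1A was higher with abemaciclib by 1.37 ± 0.23 at 1 µM (1e-05), GDF15 by 1.1 ± 0.18, CLK4 by 1.07 ± 0.18 and CLK1 by 0.93 ± 0.17 (5.55e-05), and HNRNPDL was lower (−1 ± 0.1, 3.23e-13), as were CITED2 (−1.33 ± 0.18, 2.6e-09), the YAP target CTGF (−1.6), MEPCE (−1.43), UBALD2 (−1.69) and MEIS1 (−1.42). At 3.16 µM CDKN1A (2.27 ± 0.21, 6.64e-18), GDF15 (2.01 ± 0.17), EGR1 (1.64) and TRIB3 (1.6 ± 0.16) were higher, and MEPCE (−1.98), ARL4A (−1.82), EFNA4 (−1.8) and ZBED5 (−1.72) lower. With library size alone the splits were 4 and 2 at 0.1 µM, 1 and 8 at 0.3 µM, 89 and 324 at 1 µM, and 337 and 1980 at 3.16 µM, and without MCF7 127 differed at 1 µM. Single wells gave 3, 19, 537 and 1841, and 3, 5, 287 and 1748 with plate row as a term, and CLK4 and TMEM101 at 0.3 µM lost their call.

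At 0.1 µM the mean of replication genes was lower with abemaciclib than with palbociclib (−0.12) and ribociclib (−0.19) in 7 of 7 models. At 1 µM abemaciclib differed in this mean from palbociclib by 0.04 (95.3% interval −0.08 to 0.19, exact two-sided sign-flip p = 0.562, n = 7) and from ribociclib by −0.03 (−0.13 to 0.07, exact p = 0.453), intervals that leave room for a difference. The differences at 1 µM with plate row as a term were −0.01 ± 0.05 and −0.08 (adjusted p = 0.959 and 0.304). Mitotic genes were lower with abemaciclib than with palbociclib at 1 µM by a log2 difference of −0.39 (−0.67 to −0.12) and than with ribociclib by −0.42 (−0.63 to −0.24), each in 7 of 7 models (exact p = 0.0156, adjusted p = 0.0979), and by −0.32 ± 0.07 and −0.36 with plate row as a term. ATF4 targets were higher with abemaciclib than with palbociclib by 0.22 (0.04 to 0.37, exact p = 0.0312, adjusted p = 0.133), and sterol genes at 3.16 µM by 0.27 (0.03 to 0.51, exact p = 0.0156). Ribosomal protein genes were higher than with palbociclib at 3.16 µM by 0.32 (0.18 to 0.47, exact p = 0.0156). Of 238 such list differences 64 had an exact p under 0.05 and none an adjusted p under 0.05 (smallest 0.0979). With 7 models p cannot be under 0.0156, so passing 0.05 needed very many tests at that floor.

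Between palbociclib and ribociclib edgeR and DESeq2 called 0 genes at 0.1, 0.3 and 1 µM, where 310, 473 and 306 had an unadjusted p under 0.05. At 0.1 µM 1 was called without HCC1806, MCF7, PDX-B, T47D or the third replicate. At 3.16 µM CLK1 alone differed, higher with palbociclib by 0.8 ± 0.16 (adjusted p = 0.0096, 340 genes at an unadjusted p under 0.05), and 44.5 ± 19.2 CPM (SD, n = 7 models) stood against 25.3 ± 8.65. The difference stayed above 0 but was no longer past the threshold without PDX-A (0.72, 0.999), HCC1806 (0.8, 0.0545), Hs578T (0.78, 0.0884), MCF7 (0.75, 0.393), the first (0.83, 0.18) or the third replicate (0.65, 0.999), or the outer plate rows (0.79, 0.0652). Nor was it past it with plate row as a term (0.84 ± 0.21, 0.0984). Over 7509 genes of log2 CPM 4 or more the 95% interval of this comparison reached, at the median, 0.31 on the log2 scale to either side of the estimate at 0.1, 0.3 and 1 µM and 0.3 at 3.16 µM. Replication genes differed between the drugs by −0.07 at 0.1 µM, lower with palbociclib in 7 of 7 models (−0.132 to −0.012, exact p = 0.0156, adjusted p = 0.0979; −0.03 ± 0.05 with plate row as a term), −0.07 at 1 µM (−0.165 to −0.002, exact two-sided sign-flip p = 0.0469, adjusted p = 0.174, n = 7) and −0.01 at 3.16 µM (−0.05 to 0.03, exact p = 0.781), and mitotic genes by −0.09 at 3.16 µM (exact p = 0.0312, adjusted p = 0.133).

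Abemaciclib was set against alvocidib, an inhibitor of transcription kinases. At 0.1 µM 156 genes were higher and 341 lower with abemaciclib, and at 1 µM 1662 and 1959. At 1 µM IER2 was higher with abemaciclib by 4.56 ± 0.43 (adjusted p = 4.12e-19), PLEKHF1 by 4.02, FADD by 3.81, PPRC1 by 3.8, DDIT4 by 3.78 ± 0.38, ZNF622 by 3.76, MCL1 by 2.49 ± 0.21 (2.62e-23), CCNE1 by 2.25 ± 0.64 (0.00216), CDKN1A by 1.69 ± 0.28 and MYC by 1 ± 0.28 (0.00295). CCDC80 (−1.73 ± 0.17, 5.91e-14), NAV3 (−1.66) and PLCG2 (−1.33) were lower. At 0.1 µM MEPCE was higher by 1.24 ± 0.29 (0.00256) and CCNT2 (−0.85 ± 0.19) and EREG (−1.09 ± 0.2, 0.000124) lower. Short-lived transcripts were higher at 1 µM in 35 of 40 and lower in 1 (camera adjusted p = 1.44e-21, or 8.25e-07 with an estimated correlation), and their mean differed by 2.25 (1.7 to 2.73, exact two-sided sign-flip p = 0.0156, n = 7). With library size alone the splits became 341 and 86 at 0.1 µM and 2578 and 464 at 1 µM, and without MCF7 214 differed at 0.1 µM. Single wells gave 630 at 0.1 µM and 2934 at 1 µM, and 460 and 2270 with plate row as a term.

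Within single models at 1 µM, MCF7 had the most calls with abemaciclib, 436 rises and 355 falls. Hs578T had 98 and 98 (71 and 108 with RLE factors), PDX-B 68 and 88, HCC1806 23 and 22, PDX-A 5 and 16, BT549 7 and 4, and T47D 3 and 6. In MCF7 EGR1 rose by 2.49 ± 0.22 (SE over wells, adjusted p = 2.01e-17), GDF15 by 1.61 ± 0.17 and AEN by 1.59 ± 0.15, and the mitotic gene DLGAP5 fell by 2.41. GDF15 rose by 1.87 ± 0.35 in PDX-B, with VEGFA (1.86) and SESN2 (1.65), and by 0.95 in BT549, where the splicing genes SRSF3 (−0.74 ± 0.12, 5.48e-05), SRSF7 (−0.85) and HNRNPDL (−0.8) fell. SRSF3 fell by 1.22 ± 0.18 in T47D (9.59e-07). TRIB3 rose by 0.99 in PDX-A, where the RNA sensor DDX58 (−1.93) and the p53 target PLK2 (−1.43) fell. DDIT4 rose by 1.38 and CLK1 by 1.22 in HCC1806, and BHLHE40 rose by 1.92 in Hs578T, where TWIST1 fell by 3.08 ± 0.6 (0.000339). Plate row as a term left 99 calls in Hs578T, 40 in PDX-B and 5 in BT549.

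Palbociclib at 1 µM had 9 calls in HCC1806, 8 in MCF7, 3 in Hs578T and 1 in PDX-B, and ribociclib 9 in MCF7, 3 in HCC1806, and 1 each in PDX-B and T47D. All were falls except CCND1 with palbociclib in MCF7 (0.66 ± 0.14, adjusted p = 0.0283). PCNA fell with palbociclib in HCC1806 (−0.95 ± 0.13, 9.27e-08), MCF7 (−0.86 ± 0.15, 0.00542), Hs578T (−0.68 ± 0.13) and PDX-B (−0.73 ± 0.15), was not past the threshold in T47D (−0.65 ± 0.31, 1), and with ribociclib in MCF7 (−1.05 ± 0.15, 2.68e-05) and HCC1806 (−0.66 ± 0.13, 0.00511). DTL, a ligase adaptor bound to PCNA, fell by 2.24 ± 0.44 with palbociclib in HCC1806 (0.00185), RRM2 by 1.33 ± 0.21 and GINS2 by 1.09 ± 0.19 with ribociclib in MCF7, and HMGB2 by 0.9 ± 0.19 with ribociclib in T47D. In BT549, PDX-A and T47D with palbociclib and in BT549, PDX-A and Hs578T with ribociclib edgeR and DESeq2 called 0 genes. In edgeR 299, 250, 161, 230, 222 and 249 had an unadjusted p under 0.05. With plate row as a term palbociclib had 1 call in HCC1806, 2 in MCF7 and 0 in PDX-B, and ribociclib 24 in MCF7, 2 in PDX-B and 0 in T47D.

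At the other doses of palbociclib and ribociclib 1 count within a model stood apart, that of palbociclib at 0.3 µM in PDX-B, where 104 genes rose and 44 fell (868 at an unadjusted p under 0.05), against at most 18 elsewhere. Among them were DST (1.64 ± 0.28, adjusted p = 0.000119) and CLSPN (−1.43 ± 0.27, 0.000356). The count became 580, 0 and 266 without the well in plate row A, N and P in turn, so it depended on single wells. It became 7 with plate row as a term, CLSPN among them (−1.67 ± 0.35, 0.0108). Some others changed as much but with wider standard errors, such as DHX36 (1.61 ± 0.39, then 1.64 ± 0.56) and TIPIN (−1.82 ± 0.49, then −1.89 ± 0.63), so that loss does not tell the origin.

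Alvocidib at 1 µM changed 538 genes in BT549, 894 in PDX-A, 1029 in HCC1806, 977 in Hs578T, 1882 in MCF7, 1097 in PDX-B and 662 in T47D. Short-lived transcripts fell in every model, with list scores changed by −1.85 to −1.08 (exact two-sided permutation p = 0.0119 each, adjusted p = 0.0296, 3 wells against 6). CCDC80 rose by 2.5 ± 0.13 in BT549 (2.94e-39), 2.27 in PDX-A and 3.05 in HCC1806. The counts fell to 436 in PDX-A, 673 in PDX-B and 437 in T47D with plate row as a term.

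Models, each in its own plate columns, were compared without separating model from column. The response of 249 genes of 6644 to abemaciclib at 1 µM depended on the model, of 4 of 7093 to palbociclib, 6 of 6947 to ribociclib and 205 of 6226 to alvocidib (edgeR interaction, 1026, 321, 406 and 1019 at an unadjusted p under 0.05). The 4 genes for palbociclib were PCNA, FAM111B, WDR76 and CLSPN (adjusted p of at most 0.00199). PCNA changed by −0.13 in BT549 and 0.13 in PDX-A, against −0.95 in HCC1806, −0.68 in Hs578T, −0.86 in MCF7, −0.73 in PDX-B and −0.65 in T47D. For ribociclib they were WDR76, CLSPN, PCNA, HMGB2, RRM2 and MCM10, and PCNA changed by −0.03 and 0.02 in BT549 and PDX-A against −0.61 to −1.05 elsewhere. Without MCF7 the counts were 33 for abemaciclib and 102 for alvocidib.

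As a list, replication genes differed between models with each drug. Over the 11 members measured in all 7 models, the mean change with palbociclib at 1 µM was −0.05 in BT549 and 0.08 in PDX-A, against −0.47 in HCC1806, −0.33 in Hs578T, −0.49 in MCF7, −0.38 in PDX-B and −0.51 in T47D (permutation p = 2e-05, adjusted p = 8e-05). With ribociclib it was 0.03 and 0.01 against −0.33 to −0.53 (permutation adjusted p = 0.000105), and with abemaciclib −0.1 in BT549, 0 in PDX-A, −0.1 in PDX-B and −0.77 in T47D (0.000124). Within models the score of all measured members fell with palbociclib and ribociclib at 1 µM in HCC1806, Hs578T, MCF7, PDX-B and T47D (exact two-sided permutation p = 0.0119 each, the smallest possible, 3 wells against 6) and not in BT549 (−0.04, exact p = 0.417, and 0.02, exact p = 0.536) or PDX-A (−0.002, exact p = 0.988, and −0.01, exact p = 0.881). With abemaciclib it fell in BT549 (−0.15, exact p = 0.0119) and not in PDX-A (−0.05, exact p = 0.429). Mitotic genes fell with abemaciclib at 1 µM in 6 models, PDX-A (−0.32) and BT549 (−0.25) among them (exact p = 0.0119 each). T47D was not past the threshold (−0.19, exact p = 0.226). Over common members the models differed (permutation adjusted p = 0.0358), with PDX-B at −0.68, T47D at −0.28 and the others at −0.39 to −0.24.

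In the DMSO wells CDKN2A, whose product p16 inhibits CDK4 and CDK6, had a log2 CPM of 8.82 ± 0.13 in BT549 and 7.37 ± 0.15 in PDX-A (SD, n = 6 wells) and lay between 3.43 and 4.83 in the other 5 models. RB1 lay at 5.07 in PDX-A and 4.81 in BT549 and between 3.75 and 4.4 in the others.

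How far the drugs changed the same genes was measured across genes, which are not independent replicates, for 4 pairs fixed in advance and 3 added after seeing the data. All share their DMSO libraries. Abemaciclib and alvocidib at 1 µM also share 1 plate row, and whether this adds to their agreement was not tested. At 1 µM palbociclib and ribociclib had a Pearson r of 0.41 (Spearman 0.38), where simulated groups without any change gave 0.36, and a covariance of 0.0121 against 0.0109 simulated. With 3 separate DMSO wells per model for each drug their r was 0.09 (split). Palbociclib and abemaciclib had 0.28 (0.27; simulated 0.34, split 0.07; covariance 0.0131 against 0.011), and both lowered PCNA and CLSPN, 2 genes where independent lists give 0.1. Abemaciclib and alvocidib at 1 µM had 0.23 (0.3; simulated 0.28, split 0.17; covariance 0.0459 against 0.0112), with 265 genes rising with both where independent lists give 102.5, 178 falling with both (84.4), and 60 and 18 moving apart. Palbociclib and alvocidib had 0.14 (0.17; simulated 0.31, split 0.05; covariance 0.0167 against 0.0112). Of the added pairs, abemaciclib at 1 µM and alvocidib at 0.1 µM had 0.55 (0.55; simulated 0.32, split 0.39; covariance 0.0397 against 0.0109), with 176 shared rises (15.2) and 134 shared falls (12.7). Abemaciclib at 3.16 µM had 0.56 with alvocidib at 0.1 µM (simulated 0.31, split 0.44; covariance 0.0591 against 0.0111) and 0.52 with 1 µM (simulated 0.27, split 0.48; covariance 0.154 against 0.0114).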

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

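Of the tests in this part, those of the first 2 patterns weighed were written after their result was seen, and the plate position test of the third, other than its fit with plate row as a term, and all splits of the wells but those of palbociclib at 0.3 µM were written before. In 6 of 90 groups of samples 1 member lay far from the others, where chance alone gives about 1 in 20 groups. With abemaciclib at 1 µM the log2 ratio of total counts was −0.03 in PDX-B against −0.54 to −0.36 in the other models. The mean change of short-lived transcripts was −1.02 in Hs578T with abemaciclib at 3.16 µM (others −0.16 to 0.32) and −0.15 in PDX-A with ribociclib at 3.16 µM (others 0.01 to 0.1). Among DMSO wells the mean log2 CPM of replication genes was 6.08 in replicate 6 of HCC1806 (others 6.24 to 6.32) and 6.84 in replicate 6 of T47D (others 6.27 to 6.44), and that of mitotic genes was 7.11 in replicate 3 of Hs578T (others 6.96 to 7).

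A test between models at 1 µM singled out 249 genes with abemaciclib, 4 with palbociclib, 6 with ribociclib and 205 with alvocidib. With abemaciclib the adjusted p was 6.05e-13 for HMGB2 (log2 change by model from −1.38 to 0.08), 1.33e-11 for the ribosomal protein RPSA (−0.06 to 0.89), 4.67e-10 for the matrix protein THBS1 (−1.52 to 0.4) and 4.67e-10 for EGR1 (−0.63 to 2.49). It was 5.23e-07 for S100A10, 5.23e-07 for the amino acid transporter SLC38A2 (−1.72 to −0.29), 1.03e-06 for the chaperone HSP90AA1, 1.79e-06 for the keratin KRT18 (−0.6 to 0.51), 5.18e-06 for DDIT4 (−1.95 to 1.38) and 5.79e-06 for KRT19. With palbociclib it was 2.43e-05 for PCNA, 0.000753 for FAM111B, 0.000761 for WDR76 and 0.00199 for CLSPN. With ribociclib it was 0.000682 for WDR76, 0.00208 for CLSPN, 0.00208 for PCNA, 0.0024 for HMGB2, 0.00373 for RRM2 and 0.0345 for MCM10. With alvocidib it was 1.81e-30 for KRT19 (−1.75 to 0.21), 7.76e-27 for HSPA8 (−2.53 to 0.1), 7.15e-20 for CCDC80 (0.53 to 3.05), 2.83e-19 for ubiquitin C, UBC (−2.54 to −1), and 1.54e-16 for the transcription factor KLF6 (−3.05 to 0.79). For ARL6IP1 it was 4.27e-12, for KRT18 1.05e-11, for HMGB2 2.95e-11, for PARD6B 8.08e-11 and for PLK2 4e-10.

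Lists differed between models as well, by permutation of wells, where 1e-05 is the smallest p that 100000 draws give. For replication genes the adjusted p at 1 µM was 0.000124 with abemaciclib, 8e-05 with palbociclib, 0.000105 with ribociclib and 0.000258 with alvocidib, and at 3.16 µM 4.67e-05, 4.67e-05 and 0.00014 with the first 3. Mitotic genes had 0.0358 with abemaciclib at 1 µM, 4.67e-05 at 3.16 µM (from −1.02 in PDX-B to 0.06 in T47D) and 4.67e-05 with alvocidib (−0.54 in PDX-B to 0.38 in T47D). Short-lived transcripts had 0.00166 with abemaciclib at 1 µM (−0.49 to 0.09), 4.67e-05 at 3.16 µM (−1 in Hs578T to 0.12), 0.00054 with alvocidib (−2.04 to −1.04) and 0.0114 with ribociclib at 3.16 µM. Ribosomal protein genes had 0.000178 with abemaciclib at 1 µM (−0.02 in BT549 to 0.56 in MCF7), 4.67e-05 at 3.16 µM (0.12 in T47D to 0.76 in MCF7), 0.000233 with alvocidib (0.23 to 0.76) and 0.00228 with ribociclib at 3.16 µM (−0.25 to 0.21).

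Replication genes fell with palbociclib and ribociclib in 5 models and lay near 0 in BT549 and PDX-A. Against lower depth stood the lower median total count of BT549 and PDX-A, 293007, above the median of the 7 models. Against a different set of measured list members stood the 11 common members. Their lowest mean change in BT549 and PDX-A was −0.05 at 1 µM (−0.1 at 3.16 µM). Against no difference between the models' wells stood a permutation p of 3e-05 at 1 µM, the larger of the 2 drugs (5e-05 at 3.16 µM). It does not separate model from plate column. An open and untested hypothesis is that the absence of functional RB1, known for BT549, keeps its E2F genes from responding. Its replication genes fell with abemaciclib (−0.15, exact p = 0.0119), and its RB1 transcript (log2 CPM 4.81) does not show function. CDKN2A was highest in BT549 and PDX-A (8.82 and 7.37). For PDX-A no label states the RB1 status and none was inferred.

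Ribosomal protein and mitochondrial transcripts took a larger share with abemaciclib and alvocidib. Against TMM scaling as the cause, with library size alone the ribosomal median was still 0.23 with alvocidib at 1 µM. A fall of other transcripts on a relative scale fitted its prediction, as raw ribosomal counts per well changed by −0.23 and −0.27 with abemaciclib at 1 and 3.16 µM and by −0.3 ± 0.35 (SD, n = 7 models) with alvocidib at 1 µM, and mitochondrial ones by −0.28, −0.26 and −0.13. With alvocidib at 0.1 µM they were higher in 6 of 7 models, by 0.06 ± 0.13 and 0.11 ± 0.16, so the reading stays open there. This leaves a slower decay of long-lived transcripts while synthesis falls as a hypothesis that the counts, which hold no spike-in, could not separate from a change in cell number or lysis.

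CLK1 was higher with palbociclib than with ribociclib at 3.16 µM. Against wells at a single plate position as the only cause, the lowest log2 difference without any 1 replicate or the outer plate rows was 0.65, above the 0.4 that the prediction had set. The adjusted p was nevertheless over 0.05 in 7 of those fits or fits without 1 model, so the call depended on which wells and models were used. With plate row as a term, added after the result was seen, the difference was 0.84 ± 0.21 (adjusted p = 0.0984), and whether plate rows had a part in it stays open. No biological explanation was tested.

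Other splits of the summed libraries (across models) or wells (within models) asked whether chance can be excluded for each count. Each pair of groups was fitted alone, so the real counts differ from those of the report. Given are the real count, the highest of another split and the number of splits that reach the real count, itself included. The splits keep each well in its plate row, so they do not exclude an effect of plate rows, whose layout the models share. Against DMSO across models (28 splits), abemaciclib at 0.1, 0.3, 1 and 3.16 µM had 55, 32 and 1, then 59, 13 and 1, then 483, 26 and 1, and 1524, 10 and 1. Palbociclib had 4, 11 and 6, then 17, 16 and 1, then 35, 35 and 2, and 59, 46 and 1. Ribociclib had 13, 6 and 1, then 11, 9 and 1, then 9, 6 and 1, and 30, 25 and 1. Alvocidib at 0.1 and 1 µM had 583, 64 and 1, and 4000, 81 and 1. For 12 of these 14 comparisons no other drawn split reached the real count (adjusted share 0.0417, a floor for 28 draws). As 64 splits exist, margins as thin as 17 against 16 and 11 against 9 do not exclude chance. For palbociclib at 0.1 and 1 µM chance was not excluded. With ribociclib at 0.1 µM the joint fit called no gene, so none is claimed there.

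Between drugs (28 splits, doses in the same order), abemaciclib against palbociclib had 22, 7 and 1, then 70, 38 and 1, then 283, 31 and 1, and 1254, 9 and 1. Abemaciclib against ribociclib had 15, 5 and 1, then 24, 18 and 1, then 284, 18 and 1, and 1227, 23 and 1. Palbociclib against ribociclib had 1, 4 and 10, then 0, 276 and 28, then 0, 3 and 28, and 5, 4 and 1. Abemaciclib against alvocidib had 663, 208 and 1 at 0.1 µM, and 2710, 12 and 1 at 1 µM. For 11 of 14 no other split reached the real count (adjusted share 0.0455), by a margin as thin as 5 against 4, and abemaciclib against palbociclib at 0.1 µM had no call in the joint fit, so no gene is claimed there. Among the others, 1 split of palbociclib and ribociclib at 0.3 µM held 276 genes against 0. It exchanged all models but BT549 and PDX-B, which points to opposite directions in the 2 sets of models, and the cause was not tested.

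Within models at 1 µM (84 splits, abemaciclib, palbociclib, ribociclib and alvocidib in turn), the splits of BT549 had 21, 7 and 1, then 0, 41 and 84, then 0, 5 and 84, and 453, 15 and 1. In PDX-A they had 23, 7 and 1, then 0, 14 and 84, then 1, 22 and 19, and 934, 7 and 1. In HCC1806 they had 41, 4 and 1, then 11, 6 and 1, then 4, 8 and 6, and 702, 0 and 1. In Hs578T they had 248, 15 and 1, then 3, 38 and 7, then 2, 18 and 8, and 627, 1 and 1. In MCF7 they had 819, 4 and 1, then 13, 16 and 3, then 12, 4 and 1, and 1630, 1 and 1. In PDX-B they had 219, 2 and 1, then 1, 11 and 25, then 8, 4 and 1, and 1062, 1 and 1. In T47D they had 16, 18 and 2, then 1, 9 and 20, then 1, 6 and 24, and 564, 3 and 1. Palbociclib at 0.3 µM in PDX-B had 23, 49 and 3, a share of 0.0357 for a comparison picked by its count, so no gene is claimed there. For the dependence on the model (28 splits) the 4 drugs had 249, 118 and 1, then 4, 7 and 2, then 6, 1 and 1, and 205, 111 and 1. Adjusted over comparisons, the share was under 0.05 for 17 of 28 counts within models (largest 0.0392) and 3 of 4 of model dependence (0.0476). Such splits also break up the shared drug effect, so they cannot exclude chance for the latter.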

How the results depend on the processing

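Of the alternatives, leaving out wells under 120000 counts, plate row as a term, pairing by plate row and those of palbociclib at 0.3 µM in PDX-B were chosen after seeing the data. No called gene or list changed direction under any of them. The balance of rises and falls did turn. With library size alone abemaciclib at 1 µM had 198 rises and 688 falls (404 and 373 in the report). Against alvocidib it had 2578 higher and 464 lower (1662 and 1959). As the labels carry no replicate numbers, pairing was only possible by plate row for abemaciclib at 3.16 µM. It alone had DMSO wells in all its plate rows. There 21 pairs gave 1568 genes, against 1686 in the same 42 wells with the model alone as a block (4724 tested; 2445 in the report). The setting without a filter added 1 gene across models, so it hardly tests that choice there, and with wells not summed 7119 genes were tested in place of 9273. Depth limits what could be called: with a median of 7 counts per gene and well, a change of 0.5 was recovered in 38% of simulated genes across models and 5.4% within MCF7.

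Of the results for named genes, DESeq2 left 212 on their side of the threshold and 37 not, RLE factors 244 and 5, library size alone 235 and 14, no filter 249 and 0, wells not summed 210 and 1, the outer plate rows left out 223 and 26, plate row as a term 166 and 45, and wells under 120000 counts left out 242 and 7. Leaving out 1 model left 1485 and 258, and leaving out 1 replicate 591 and 156. Gene list calls were kept in 61 of 62 with library size alone and with RLE factors, in 56 with plate row as a term, and in 410 of 434 fits without 1 model. No total count passed the adjusted sign-flip test in any fit. The 3 lowered totals stayed below 0 without any 1 model, from −0.43 to −0.35 and −0.52 to −0.37 with abemaciclib at 1 and 3.16 µM and −0.6 to −0.46 with alvocidib at 1 µM. Abemaciclib at 0.3 µM, however, reached 0.04 and ribociclib at 3.16 µM 0.01 without PDX-A. With the plate row effect removed the 3 totals were −0.25, −0.55 and −0.44, and 5 small ones changed sign: palbociclib at 0.1, 1 and 3.16 µM (0.08, 0.06 and 0.16, then −0.06, −0.05 and −0.06) and ribociclib at 0.3 and 1 µM (0.05 and −0.13, then −0.05 and 0.05).

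With wells not summed, counts of genes against DMSO became 25 and 79 for abemaciclib at 0.1 and 0.3 µM (11 and 28 in the report), 52, 25 and 47 for palbociclib at 0.3, 1 and 3.16 µM (5, 2 and 15), 6, 15 and 25 for ribociclib (1, 2 and 10) and 1035 for alvocidib at 0.1 µM (666). The difference of abemaciclib from palbociclib at 0.1 µM became 3 (0), and from ribociclib at 0.3 µM 19 (9). The cause was not tested.

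Plate row as a term was fitted to wells not summed, so brackets hold the count of wells not summed, then that of the report. Against DMSO counts became 6 for abemaciclib at 0.1 µM (25, 11), 1, 2 and 13 for palbociclib at 0.3, 1 and 3.16 µM (52, 5; 25, 2; 47, 15), 1, 1 and 5 for ribociclib (6, 1; 15, 2; 25, 10) and 269 for alvocidib at 0.1 µM (1035, 666). Abemaciclib differed from palbociclib in 3, 3 and 211 at 0.1, 0.3 and 1 µM (3, 0; 21, 17; 620, 499), from ribociclib at 0.3 µM in 5 (19, 9) and from alvocidib at 1 µM in 2270 (2934, 3621), and palbociclib from ribociclib at 3.16 µM in 0 (1, 1). Within models, fitted on wells throughout, abemaciclib at 1 µM had 5 in BT549 (11), 99 in Hs578T (196) and 40 in PDX-B (156), palbociclib 1 in HCC1806 (9), 2 in MCF7 (8) and 0 in PDX-B (1), ribociclib 24 in MCF7 (9), 2 in PDX-B (1) and 0 in T47D (1), and alvocidib 436 in PDX-A (894), 673 in PDX-B (1097) and 437 in T47D (662). Palbociclib at 0.3 µM in PDX-B had 7 (148), and 76 with DESeq2. The cause was not tested.

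Without the outer plate rows abemaciclib at 0.1 µM had 7 genes, palbociclib 26 at 0.3 µM and 4 at 1 µM, ribociclib 0 at 0.3 µM and 0 at 1 µM, and alvocidib at 0.1 µM 397. Abemaciclib differed from palbociclib at 0.3 µM in 184 (17 in the report), from ribociclib at 0.3 µM in 4 and from alvocidib at 0.1 µM in 240 (497), and palbociclib from ribociclib in 8 at 0.3 µM (0) and 0 at 3.16 µM (1). With library size alone abemaciclib at 0.3 µM had 46, and differed from ribociclib at 0.1 µM in 6 (2). With RLE factors ribociclib had 2 at 0.3 µM and 0 at 1 µM, and within models 1 in Hs578T (0) and 2 in PDX-B (1). With no filter palbociclib had 4 in MCF7 (8), and ribociclib 3 in PDX-B (1) and 2 in T47D (1). Without wells under 120000 counts palbociclib at 0.3 µM had 2 and ribociclib at 1 µM 0. The cause was not tested.

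With DESeq2 palbociclib at 0.3 µM had 23, ribociclib 0 at 0.3 µM and 5 at 3.16 µM, and abemaciclib differed from ribociclib in 5 at 0.1 µM and 17 at 0.3 µM. Within models at 1 µM DESeq2 called 309 with alvocidib in BT549 (538), 12 with abemaciclib and 573 with alvocidib in PDX-A (21 and 894), 1 with palbociclib and 0 with ribociclib in HCC1806 (9 and 3), 124 with abemaciclib and 540 with alvocidib in Hs578T (196 and 977), 2 with palbociclib and 4 with ribociclib in MCF7 (8 and 9), 93 with abemaciclib and 0 with ribociclib in PDX-B (156 and 1), and 3 with abemaciclib, 0 with ribociclib and 426 with alvocidib in T47D (9, 1 and 662). The cause was not tested.

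Leaving out 1 model gave, against DMSO, 5 to 22, 12 to 42, 296 to 823 and 1701 to 2471 genes with abemaciclib at 0.1, 0.3, 1 and 3.16 µM, 0 to 0, 0 to 13, 0 to 18 and 2 to 42 with palbociclib, 0 to 0, 0 to 7, 0 to 11 and 0 to 19 with ribociclib, and 292 to 675 and 3835 to 4298 with alvocidib at 0.1 and 1 µM. At these doses abemaciclib differed from palbociclib in 0 to 1, 3 to 24, 156 to 461 and 1424 to 2004, from ribociclib in 0 to 3, 4 to 17, 127 to 437 and 1397 to 1967, and from alvocidib in 214 to 484 and 3154 to 3545, and palbociclib from ribociclib in 0 to 1, 0 to 0, 0 to 0 and 0 to 1. List differences with an exact p under 0.05 numbered 39 to 48 (64), gene list calls 59 to 71 (62), and model dependence 33 to 264 genes with abemaciclib, 1 to 6 with palbociclib, 2 to 10 with ribociclib and 102 to 192 with alvocidib.

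Leaving out 1 replicate gave, in the same order, 4 to 14, 18 to 21, 272 to 560 and 1529 to 2006 with abemaciclib, 0 to 0, 0 to 18, 0 to 7 and 7 to 14 with palbociclib, 0 to 1, 0 to 4, 1 to 3 and 1 to 3 with ribociclib, and 303 to 377 and 3346 to 3873 with alvocidib. Abemaciclib differed from palbociclib in 0 to 1, 6 to 18, 191 to 364 and 1209 to 1481, from ribociclib in 0 to 5, 6 to 11, 164 to 178 and 1013 to 1606, and from alvocidib in 135 to 308 and 2246 to 3088, and palbociclib from ribociclib in 0 to 1, 0 to 0, 0 to 0 and 0 to 1. Model dependence had 53 to 139 genes with abemaciclib, 1 to 3 with palbociclib, 0 to 3 with ribociclib and 55 to 99 with alvocidib.

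Within models at 1 µM, leaving out 1 replicate gave 5 to 16, 0 to 0, 0 to 0 and 291 to 634 genes in BT549 (abemaciclib, palbociclib, ribociclib and alvocidib in turn), 7 to 18, 0 to 0, 0 to 0 and 480 to 902 in PDX-A, 11 to 56, 1 to 10, 0 to 3 and 701 to 1041 in HCC1806, 45 to 162, 1 to 3, 0 to 2 and 484 to 909 in Hs578T, 430 to 786, 0 to 7, 2 to 13 and 1158 to 1902 in MCF7, 23 to 136, 0 to 1, 0 to 3 and 551 to 1068 in PDX-B, and 6 to 12, 0 to 1, 0 to 1 and 347 to 678 in T47D. Palbociclib at 0.3 µM in PDX-B had 0 to 414.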

Other observations

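The genes in this part were chosen after their values were seen, and no further test was added. Single members of lists that were not called as a whole moved. With abemaciclib at 1 and 3.16 µM the mRNA decay factor ZFP36L2 fell by 0.66 ± 0.11 (adjusted p = 1.44e-05) and by 1.42 ± 0.13 (8.2e-18), and the AP-1 subunit FOSL1 rose by 0.72 ± 0.14 (0.000259) and by 1.12 ± 0.14 (4.53e-10).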
